A study of Homo sapiens with 20 samples.

How the data were processed

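RNA of 10 human T-cell acute lymphoblastic leukemia (T-ALL) cell lines was measured on 20 Affymetrix 3' expression arrays. Each line gave 1 array after vehicle (DMSO) and 1 array after 100 nM of CompE, a gamma-secretase inhibitor, both at 72 h. Per the labels' protocols, total RNA was extracted with a column kit and labelled with biotin by the manufacturer's standard procedure. The values deposited by the authors are MAS5 signal intensities on a linear scale, per the submitters' processing notes; the version and settings of that program are not given in the sources used here. Tested on the values, the mean of each array without its highest and lowest 2% of probe sets was 250 on all 20 arrays, which shows that the authors scaled every array to 1 target. The scaling was kept. MAS5 subtracts signal of mismatch probes, so its values are noisy near 0, and a scaling to a common mean cannot show a change in the total amount of RNA per cell. Detection calls were not used here.

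The table held 22277 probe sets, of which 62 were control probe sets and were left out of all gene tests. The platform's annotation table gave 1 gene for 19070 probe sets and several genes for 1043, and it did not list 2164. Only probe sets with 1 gene were named. Of these outside the controls, 19052 matched the RefSeq gene table by gene identifier and 0 symbols needed an update. Together they covered 11963 genes. For each gene the probe set with the highest mean over all arrays was used, and genes whose probe set lay under the 40th percentile of mean log2 signal (a signal of about 32.5) were left out, which left 7695 genes. Of them, 3295 had several probe sets, and disagreements among these are given beside some of the called genes named. Probe sets under the filter were mostly left out there. Their log2 changes under CompE included 0.069 for NOTCH3, 0.308 for HES1, 0.064 for CDKN2D, 0.071 for CACNG4, 0.179 for IL23A, 0.248 for NOP16 and -0.229 for PDAP1. Probe sets of HES4, HES5, DTX1 and NRARP were not analysed here. Some planned items are not reported here. The binding data named in the series' description were not analysed here.

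Signals were analysed as log2(signal + 16), so changes are on that scale and understate the fold of dim genes. The change under CompE was fitted per gene in limma 3.58.1 (R 4.3.3) with cell line as a fixed block, an intensity trend in eBayes and Benjamini-Hochberg adjustment over the 7695 genes at 0.05, two-sided. In 3 lines (CCRF-CEM, MOLT3 and P12-ICHIKAWA) the DMSO label names another growth medium than the CompE label. The name is that of the cell line RPMI8402, so the entry may be an error; whether the medium differed is not settled, and an alternative left these lines out. The pairing comes from the labels, which name the line of every array, and all 10 CompE arrays correlated best with the DMSO array of their own line. The prior degrees of freedom were 7.39 beside 9 residual ones. The labels do not say whether the arrays of a line came from separate cultures; the lines are the replicates, and p-values measure the spread between these 10 lines. With 10 pairs, the number of arrays limits the precision of every value.

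Gene lists fixed from general knowledge before the data were examined were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 17 lists. They were NOTCH targets, nucleolar ribosome biogenesis, MYC-linked growth and nucleotide metabolism, DNA replication, mitosis, ATF4 and amino acid synthesis, cholesterol synthesis, thymocyte and T-cell differentiation, growth arrest and FOXO-linked genes, apoptosis regulators, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, gamma-secretase subunits, interferon-stimulated genes, lysosome and autophagy, and T-ALL subtype oncogenes and suppressors. Camera with an estimated correlation, and fry, which tests a list without comparing it with other genes, served as alternatives. Markers of B cells, myeloid, erythroid and epithelial cells and fibroblasts were fixed in the same way. Mean changes per line were tested with exact sign-flip permutation tests over 10 pairs (1024 patterns, two-sided, smallest p 0.00195). Relations across lines were tested with Pearson's r and Spearman's rho with permutation p. Genes named in the text are the 12 largest falls and the 12 largest rises among genes past the threshold that moved that way in at least 8 of 10 lines, up to 4 tested members of each list with the smallest adjusted p, and a fixed set of NOTCH pathway genes and gamma-secretase subunits. Other genes were chosen after their values were seen, and the text says so.

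The code was tested on simulated data with 7695 genes and the same 20 arrays. Over 5 rounds with 200 changed genes, it recovered 62.8% of changes of 0.5 log2, 99.2% of changes of 1 and 100% of larger ones, and 4.74% of calls were false. With no effect it made 1 call, and it called 0 lists. The simulated noise was drawn independently for each gene, so this cannot show how often camera calls lists with correlated members. In the real data the estimated correlation reached 0.708, for cytosolic ribosomal proteins. The simulation also gave a gene the same noise SD on all arrays and the same change in all lines. The real lines differed in both, with an SD of changes over genes from 0.327 in CCRF-CEM to 0.726 in KOPTK1. The simulated rates may therefore not hold for the real data. The alternatives tried before or after the data were examined were the block, the scaling, the pseudocount, the filter, the choice of probe set, the variance model, lines left out, RNA quality and signal floor as covariates, and exact tests.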

Results

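T-ALL cell lines, 10 in number, that carry activating NOTCH1 mutations, per the series' description, were compared with and without a gamma-secretase inhibitor. Gamma-secretase is the protease complex that cuts NOTCH receptors in the membrane and so frees their active intracellular part. The lines were ALL-SIL, CCRF-CEM, CUTLL1, DND41, HPB-ALL, KOPTK1, MOLT3, P12-ICHIKAWA, PF382 and RPMI8402, all established from human T-cell leukemias or lymphomas. Each line had 1 array after DMSO and 1 after 100 nM CompE for 72 h, 20 arrays in all. Median signals of the arrays lay between 54.7 and 74.8, and the highest signal was 17617. In CCRF-CEM, MOLT3 and P12-ICHIKAWA the DMSO label names another growth medium than the CompE label. The name given there is that of the cell line RPMI8402, so the entry may be an error, and whether the medium differed is not settled. The question was which genes respond when NOTCH1 signalling is inhibited.

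The lines differed from each other far more than they changed under treatment. Cell line accounted for 87.2% of the total sum of squares of the 7695 tested genes, treatment for 3.0% and the residual for 9.8%. Each CompE array correlated with the DMSO array of its own line at r = 0.918 to 0.984 across genes, and with that of any other line at 0.912 at most. Oncogenes that define T-ALL subtypes were high in some lines and dim in the others. TLX1, a homeobox gene, had a signal of 913 in DMSO and 763 in CompE in ALL-SIL, and at most 28.2 in the other lines. The related TLX3 reached 302 and 260 in DND41 and 268 and 174 in HPB-ALL, against at most 65.3 elsewhere. In RPMI8402, NKX2-1 stood at 352 and 290, LMO1 at 595 and 136, and LYL1 at 1050 and 1200. LYL1 was also high in CCRF-CEM, at 526 and 816, as was MEF2C at 265 and 477; in RPMI8402 MEF2C stood at 245 and 299. LMO2, a transcriptional cofactor, was highest in KOPTK1, at 3840 in DMSO and 1150 in CompE, followed by P12-ICHIKAWA at 1200 and 1000. TAL1 was highest in PF382, at 671 and 788, followed by RPMI8402 at 580 and 759, CCRF-CEM at 241 and 336 and KOPTK1 at 135 and 203. The cell cycle inhibitor CDKN2A reached 1960 in DND41 and 1400 in HPB-ALL in DMSO. These levels are single arrays and were not tested; the genes were picked from the fixed list after their levels were seen.

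The arrays differed in RNA quality, and this moved with treatment. The ratio of 3' to 5' signal of ACTB, which rises as RNA is degraded, was 1.47 ± 0.687 in DMSO and 2.28 ± 2.64 in CompE (SD, n = 10). It was higher in CompE in 9 of 10 lines, in PF382 by 0.003 on the log2 scale (exact sign-flip p = 0.00586, 0.0244 after Benjamini-Hochberg over 5 measures). KOPTK1 stood apart at 3.32 and 9.76, and without it the exact p was 0.0117. The GAPDH ratio was 1.01 ± 0.126 against 1.19 ± 0.415, higher in 8 lines (exact p = 0.0312, adjusted 0.052), and without KOPTK1 its exact p was 0.0625. The bacterial control BioB, added in a fixed amount by the standard procedure, read 224 ± 68.2 in DMSO and 264 ± 68.8 in CompE, higher in 9 of 10 lines (exact p = 0.00977, adjusted 0.0244). The 10th percentile of signal was 3.95 ± 0.787 and 5.28 ± 2.05 (exact p = 0.0605, adjusted 0.0756).

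Under CompE, direct targets and components of NOTCH signalling were among the genes that fell most. HES1, a transcriptional repressor induced by NOTCH, fell by 1.71 ± 0.304 on the log2 scale (SE, n = 10 pairs, limma adjusted p = 0.00775) and was lower in all 10 lines. CR2, the complement receptor CD21, fell by 1.95 ± 0.393 (adjusted p = 0.0127), and the receptor NOTCH3 fell by 1.34 ± 0.233 (adjusted p = 0.00692), each in 9 lines. MYC, the transcription factor that drives cell growth, fell by 1.5 ± 0.282 (adjusted p = 0.0107), from a mean signal of 1810 to 629. Its change was -3.85 in KOPTK1 and 0.53 in P12-ICHIKAWA, the 1 line where it was higher. The NOTCH-regulated long noncoding RNA LUNAR1 fell by 0.85 ± 0.178 (adjusted p = 0.0142) in all 10 lines.

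The remaining largest falls were those of 7 genes. The amino acid transporter SLC7A5 fell by 1.17 ± 0.232, the translation repressor EIF4EBP1 by 1.05 ± 0.237 and the mitochondrial protein C1QBP by 0.96 ± 0.145, the last in all 10 lines. The chromatin helicase HELLS had a change of -1.02, ID1, an inhibitor of basic helix-loop-helix factors, -1.01, PDAP1 -0.94 and EIF5A -0.93. Limma's adjusted p for these 7 genes lay between 0.00448 and 0.0471. Other probe sets of EIF5A changed by -0.09 and -0.05, and with the mean of its probe sets it was at -0.35 (adjusted p = 0.204). A second bright probe set of HES1 changed by -0.63. Of 16 alternatives, 3 of which ended the call of every named gene, HELLS passed in 7, EIF5A in 6 and PDAP1 in 5. With the ACTB ratio as a covariate, CR2 (-1.61 ± 0.471, limma adjusted p = 0.0624) and MYC (-1.06 ± 0.299, adjusted p = 0.057) were not past the threshold, while HES1 (-1.78, adjusted p = 0.0239) and NOTCH3 (-1.27, adjusted p = 0.0299) were. The log2 ACTB ratio changed by 1.557 in KOPTK1 and by -0.049 to 0.542 in the other lines, so KOPTK1 weighs heavily in that covariate. In the fit that left KOPTK1 out, CR2 and MYC were past the threshold. Over all alternatives the adjusted p ranged from 0.0121 to 0.977 for CR2, from 0.00461 to 0.829 for MYC, from 0.00692 to 0.903 for HES1 and from 0.00628 to 0.977 for NOTCH3, the highest being without the block of lines.

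RASGRP1, an activator of RAS in T cells, rose by 0.87 ± 0.121 (limma adjusted p = 0.00448) in all 10 lines, from a mean signal of 1230 to 2260. The cytokine gene LTB rose by 1.08 ± 0.226 (adjusted p = 0.0144), and the surface receptor CD96 by 0.82 ± 0.229 (adjusted p = 0.0428). SH3GL3, of the endophilin family, rose by 1.24 ± 0.306 (adjusted p = 0.026), in all 10 lines, but its other probe sets changed by 0.11 and 0.62, and with the mean of probe sets it was not called (0.68, adjusted p = 0.0763). RECK, an inhibitor of metalloproteinases, rose by 1.07 (adjusted p = 0.0271). RHEX was at 1.06 (adjusted p = 0.0428) and TENM1 at 0.99 (adjusted p = 0.0498), calls that few alternatives kept: of 15, RHEX passed in 2 and TENM1 in 1. CD96 passed in 6 of 16 and not with a random block (adjusted p = 0.199), and SLC6A13 in 4 of 15. A second bright probe set of RECK changed by 0.16, and a dim one of RHEX by 0.00. The remaining largest rises were dim in DMSO: IGHM at a signal of 48.2 rose by 0.92, IL23A at 38.3 by 0.87, CYTH4 at 79.0 by 0.80, SLC6A13 at 24.1 by 0.80 and CACNG4 at 53.9 by 0.80. Changes of the other probe sets of IGHM ranged from -0.52 to 0.54, and with the mean of its probe sets it was not called (0.32, adjusted p = 0.324). Single lines carried part of some rises: without MOLT3 the change of RECK was 0.78, and without HPB-ALL that of TENM1 was 0.66 and that of CD96 0.55.

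**Figure D1:**
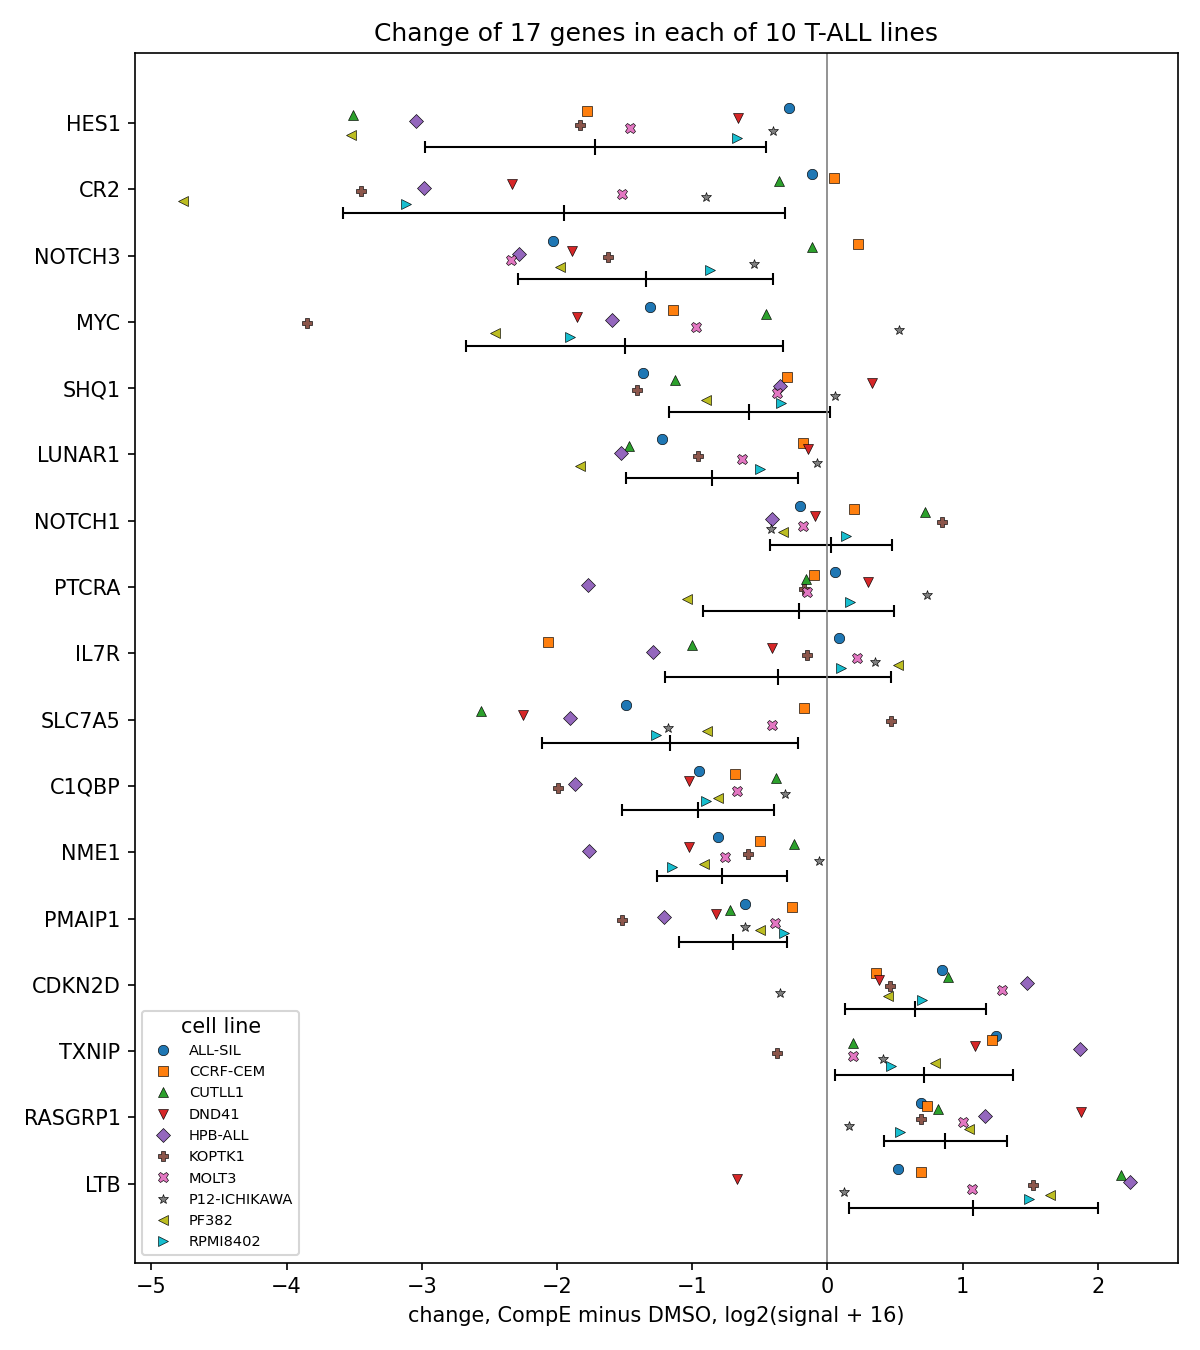
Change of 17 genes under CompE in each of 10 T-ALL lines, as CompE minus DMSO on the log2(signal + 16) scale; each symbol is 1 line, and the black bar is the mean ± SD over lines. HES1 and LUNAR1 lay below 0 in all 10 lines, and MYC ranged from -3.85 in KOPTK1 to 0.53 in P12-ICHIKAWA.

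In all, 552 of 7695 genes changed, 303 higher and 249 lower in CompE (limma, Benjamini-Hochberg 0.05), and 217 of them moved the same way in all 10 lines. Of 51 named genes that passed, 26 also passed in every fit that left out 1 line, among them HES1, CR2, MYC, NOTCH3, SLC7A5, C1QBP, LUNAR1, LTB, IGHM, RASGRP1, IL23A and CYTH4. At 1.5-fold or more were 59 that rose and 44 that fell, and at 2-fold or more 4 and 8. With each array centred on its median, 200 were higher and 289 lower. The count rested on which lines were in it: 181 without HPB-ALL, 183 without RPMI8402, 214 without DND41, 316 without CUTLL1, 346 without MOLT3, 355 without PF382 and 1031 without KOPTK1. It was 318 with the ACTB ratio as a covariate, and 0 with the 10th percentile of signal as one, with exact sign-flip tests, or without the block of lines (1045, 1851 and 369 genes at an unadjusted p under 0.05, against 1934).

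The list of NOTCH targets moved down as a group. Of 14 tested members, 6 fell (CR2, HES1, MYC, NOTCH3, LZTFL1 and SHQ1) and 1 rose, TRIB2, by 0.38; adjusted over the list alone, 7 fell and 2 rose. LZTFL1 and TRIB2 were named after their values were seen. SHQ1, an assembly factor of small nucleolar ribonucleoproteins, fell by 0.58 ± 0.153 (limma adjusted p = 0.0346). It was not past the threshold with the ACTB ratio as a covariate (-0.52, limma adjusted p = 0.116). It passed in 10 of 16 alternatives and in 4 of the 10 fits that left out a line. NOTCH1 itself was at 0.03 ± 0.123, PTCRA, the pre-T-cell receptor chain, at -0.21 ± 0.186, and the interleukin receptor IL7R at -0.36 ± 0.218, and none of these passed the test. Single lines moved these values: PTCRA was at -0.04 without HPB-ALL, -0.12 without PF382 and -0.32 without P12-ICHIKAWA, IL7R at -0.17 without CCRF-CEM, and NOTCH1 ranged from -0.06 to 0.08 when 1 line was left out. By its other probe sets PTCRA changed by -0.531 and -0.355, and it passed in 0 of 16 alternatives. The camera test gave adjusted p = 1.52e-04, and adjusted p = 0.0476 with an estimated correlation. The mean change per line was -0.60 ± 0.277 (SD, n = 10), below 0 in 10 of 10 lines (exact p = 0.00195), and ran from -1.08 in PF382 to -0.11 in P12-ICHIKAWA. Many of these targets were described in T-ALL lines such as these, so the list is not independent evidence of its direction. The ACTB ratio was higher in CompE in 9 of the same 10 lines; with it as a covariate, 7 of the 8 lists called by camera were still past the threshold, the exception being lysosome and autophagy. Those calls used the preset correlation, and KOPTK1 weighs heavily in the covariate, so they cannot exclude an effect of RNA quality. With DMSO and CompE exchanged within lines, 13 of 100 splits called 8 or more lists, so each list is given with its test per line or with an estimated correlation.

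Of 19 members of the MYC-linked growth and nucleotide metabolism list, 10 fell and 0 rose; adjusted over the list alone, 14 fell. Examples were the nucleotide kinase NME1, by 0.78 ± 0.129, the mitochondrial chaperonin HSPE1, by 0.58 ± 0.099, and the purine synthesis enzymes GART, by 0.46 ± 0.087, and ATIC, by 0.43 ± 0.082, all lower in 10 lines (limma adjusted p from 0.00692 to 0.0113). Camera gave adjusted p = 2.68e-12, and adjusted p = 0.064 with an estimated correlation. Of 19 nucleolar ribosome biogenesis genes, 7 fell and 0 rose, and 12 fell adjusted over the list alone. Among them were NIP7 (-0.58 ± 0.134), MRTO4 (-0.54 ± 0.122), NOP16 (-0.53 ± 0.112) and WDR12 (-0.35 ± 0.079), with limma adjusted p from 0.015 to 0.0207. Camera gave adjusted p = 1.37e-09 for the list, and adjusted p = 0.064 with an estimated correlation. Per line, the MYC-linked list changed by -0.34 ± 0.190, below 0 in 10 lines (exact p = 0.00195), and the nucleolar list by -0.31 ± 0.195, below 0 in 9 lines (exact p = 0.00391), with KOPTK1 at 0.05. The 13 cytosolic ribosomal proteins tested had 0 members called either way, RPL19 being at 0.20 ± 0.066. Their list was not called (camera adjusted p = 0.51), but quantile normalization placed it lower (adjusted p = 0.0176), and it was called higher without DND41 (adjusted p = 0.033); over its alternatives the adjusted p ranged from 0.0176 to 0.975.

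In the ATF4 and amino acid synthesis list, 3 of 19 genes fell, also adjusted over the list alone: SLC7A5, the glycyl-tRNA synthetase GARS1 (-0.52 ± 0.104, limma adjusted p = 0.0127) and MTHFD2 of mitochondrial folate metabolism (-0.58 ± 0.160, adjusted p = 0.0413, past the threshold in 7 of 16 alternatives). PHGDH, the first enzyme of serine synthesis, was at -0.60 ± 0.213 and was not called, though it was without KOPTK1 (-0.74, adjusted p = 0.0249). Camera gave adjusted p = 7.89e-06, with adjusted p = 0.269 with an estimated correlation and 0.125 in fry. Of 17 oxidative phosphorylation genes, 2 fell, CYC1 and ATP5MC1, each by 0.40, and 4 fell adjusted over the list alone. ATP5MC1 passed in 10 of 16 alternatives and in 4 of the 10 fits that left out a line. COX5B (-0.28 ± 0.083) and NDUFS1 (-0.28 ± 0.085) did not pass over all genes, but COX5B passed without KOPTK1 (adjusted p = 0.0206), NDUFS1 without P12-ICHIKAWA (adjusted p = 0.0402), and both with a random block (adjusted p = 0.0298 and 0.0429). Camera gave adjusted p = 6.29e-04, with adjusted p = 0.179 with an estimated correlation and 0.00996 in fry. Per line the list changed by -0.12 ± 0.099, below 0 in 9 lines (exact p = 0.00391). Glycolysis was not called (adjusted p = 0.994): GAPDH rose by 0.28 ± 0.078 (limma adjusted p = 0.0449) and was the 1 called gene of 18, also adjusted over the list alone, though not with median centring (0.24, adjusted p = 0.11), while HK2 was at -0.35, PFKM at -0.22 and PGK1 at 0.14, or -0.03 with the mean of its probe sets. GAPDH passed in 1 of the 10 fits that left out a line, and its adjusted p over the alternatives ranged from 0.0277 to 0.977. Cholesterol synthesis had 0 called genes of 14 (adjusted p = 0.9), with LSS at 0.30, IDI1 at 0.23, INSIG1 at 0.23 and MSMO1 at -0.16. LSS was called without CCRF-CEM (0.36, adjusted p = 0.0448) and INSIG1 without KOPTK1 (0.37, adjusted p = 0.0326), but INSIG1 was at 0.12 without MOLT3, and MSMO1 at -0.08 without HPB-ALL and -0.10 without KOPTK1.

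None of the 22 tested DNA replication genes was called over all genes and 3 were lower adjusted over the list alone, with GINS2 at -0.57 ± 0.168, CDC6 at -0.47 ± 0.142, MCM4 at -0.40 ± 0.122 and MCM6 at -0.27 ± 0.097. Without KOPTK1, GINS2 and MCM4 were called (adjusted p = 0.0326 and 0.0279), as were GINS2 without P12-ICHIKAWA (0.0322) and CDC6 without MOLT3 (0.043), and all 3 with a random block or median centring (adjusted p from 0.0376 to 0.0483). As a list they were lower in camera (adjusted p = 2.61e-06), a call lost with an estimated correlation (adjusted p = 0.375) and in fry (adjusted p = 0.195). Per line the mean was -0.25 ± 0.423 and below 0 in 7 of 10 lines (exact p = 0.0762), with HPB-ALL at -1.03 and CUTLL1 at -0.98. Without KOPTK1 it was -0.29 (exact p = 0.0391, n = 9) and with median centring -0.29 (exact p = 0.0371). It was -0.16 without HPB-ALL and -0.17 without CUTLL1 (exact p = 0.152 for each, n = 9). The 20 mitosis genes had 0 calls (camera adjusted p = 0.51), with TOP2A at 0.16, TTK at 0.16, CCNB2 at 0.14 and NUSAP1 at 0.13. TOP2A was called without KOPTK1 (0.23, adjusted p = 0.0445). Their mean per line was 0.06 ± 0.193 (exact p = 0.344), and from 0.03 to 0.10 when 1 line was left out. With the mean of all probe sets, TOP2A and NUSAP1 lay at -0.01 and -0.04.

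In the growth arrest and FOXO-linked list, 4 of 17 genes rose and 0 fell, and 8 rose adjusted over the list alone. The 4 were TXNIP, a regulator of glucose uptake (0.71 ± 0.167), the cyclin-dependent kinase inhibitor CDKN2D (0.65 ± 0.141), PIK3IP1, an inhibitor of PI3 kinase (0.61 ± 0.132), and the cyclin CCNG2 (0.45 ± 0.104), with limma adjusted p from 0.016 to 0.0212. Other probe sets of TXNIP changed by 0.26 and 0.33, and it was not called with the mean of probe sets (0.44, adjusted p = 0.101) or with a random block (adjusted p = 0.216). CCNG2 was not called in the same settings (adjusted p = 0.0751 and 0.0537), nor PIK3IP1 with the ACTB ratio as a covariate (adjusted p = 0.0707). Camera gave adjusted p = 1.03e-04, and adjusted p = 0.092 with an estimated correlation. Per line the list changed by 0.32 ± 0.166, above 0 in 10 lines (exact p = 0.00195). In the lysosome and autophagy list, 2 of 17 rose, also adjusted over the list alone: the autophagy kinase ULK1, by 0.56 ± 0.107, and the lysosomal membrane protein LAMP1, by 0.33 ± 0.072. ATP6V1H was at 0.24 and MAP1LC3B at 0.25, and neither was called, though both were without KOPTK1 (adjusted p = 0.0334 and 0.0245). Camera gave adjusted p = 0.0213, and adjusted p = 0.105 with an estimated correlation. That list was also not called with the ACTB ratio as a covariate (adjusted p = 0.0556), with the mean of all probe sets (0.0901) or without the block of lines (0.0733), and its adjusted p over the alternatives ranged from 0.00168 to 0.105. Its mean per line was 0.16 ± 0.101, above 0 in 10 lines (exact p = 0.00195). Other probe sets of LAMP1 changed by 0.18, -0.04 and -0.43, and with the mean of its probe sets it was at 0.01 (adjusted p = 0.966).

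The apoptosis list was not called (camera adjusted p = 0.499). PMAIP1 and BID, which promote cell death, fell by 0.70 ± 0.113 and 0.41 ± 0.083 in all 10 lines (limma adjusted p = 0.00641 and 0.0127). BCL2L1, which opposes it, was at 0.55 ± 0.159 (adjusted p = 0.0468), with other probe sets at -0.09 and 0.02; it passed in 4 of 16 alternatives and in 2 of the 10 fits without a line, and was at 0.16 with the mean of probe sets (adjusted p = 0.528). CFLAR was at -0.29 and was not called over all genes; adjusted over the list alone, 3 of 12 fell and 1 rose. Of 26 thymocyte and T-cell genes, the kinase LCK rose by 0.26 ± 0.062 and the transcription factor GATA3 by 0.30 ± 0.075, and CD3G of the T-cell receptor complex fell by 0.54 ± 0.135 (limma adjusted p from 0.0228 to 0.0271). LCK and GATA3 were not called with a random block (adjusted p = 0.299 and 0.108) or with median centring (0.0768 and 0.0546), each passing in 8 of 16 alternatives, and CD3G in 10. LEF1 was at 0.19, not called over all genes but called without KOPTK1 (0.22, adjusted p = 0.0221), with other probe sets at -0.07 and -0.26, and 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.733). Among 13 interferon-stimulated genes, IRF7 rose by 0.60 ± 0.123 (limma adjusted p = 0.0138), alone also when adjusted over the list alone. IRF9 was at 0.36, IFIT1 at -0.21 (-0.11 without KOPTK1) and XAF1 at -0.19 (-0.05 without ALL-SIL). Without CCRF-CEM, MOLT3 and P12-ICHIKAWA, IRF9 was called (0.56, limma adjusted p = 0.0474) and IRF7 was not (0.53, adjusted p = 0.0729). The list was not called (camera adjusted p = 0.946); its mean was 0.02 and its median -0.04. The 5 gamma-secretase subunits tested had 0 calls (camera adjusted p = 0.994), with NCSTN at 0.19 ± 0.086, APH1B at 0.17 ± 0.194, APH1A at 0.03 ± 0.099, PSENEN at -0.09 ± 0.119 and PSEN2 at -0.16 ± 0.156. When 1 line was left out APH1B ranged from 0.09 to 0.34, APH1A from -0.03 to 0.08, PSENEN from -0.14 to -0.02 and PSEN2 from -0.20 to -0.07. The 7 tested T-ALL oncogenes and suppressors had 0 calls (camera adjusted p = 0.554), also adjusted over the list alone, with FBXW7 at 0.39, TAL1 at 0.35, LMO2 at -0.28 and MYB at 0.10, or -0.61 by its other probe set. LMO2 was at -0.12 without KOPTK1, and MYB at 0.16 without HPB-ALL. This list too was drawn from work on such lines.

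**Figure D2:**
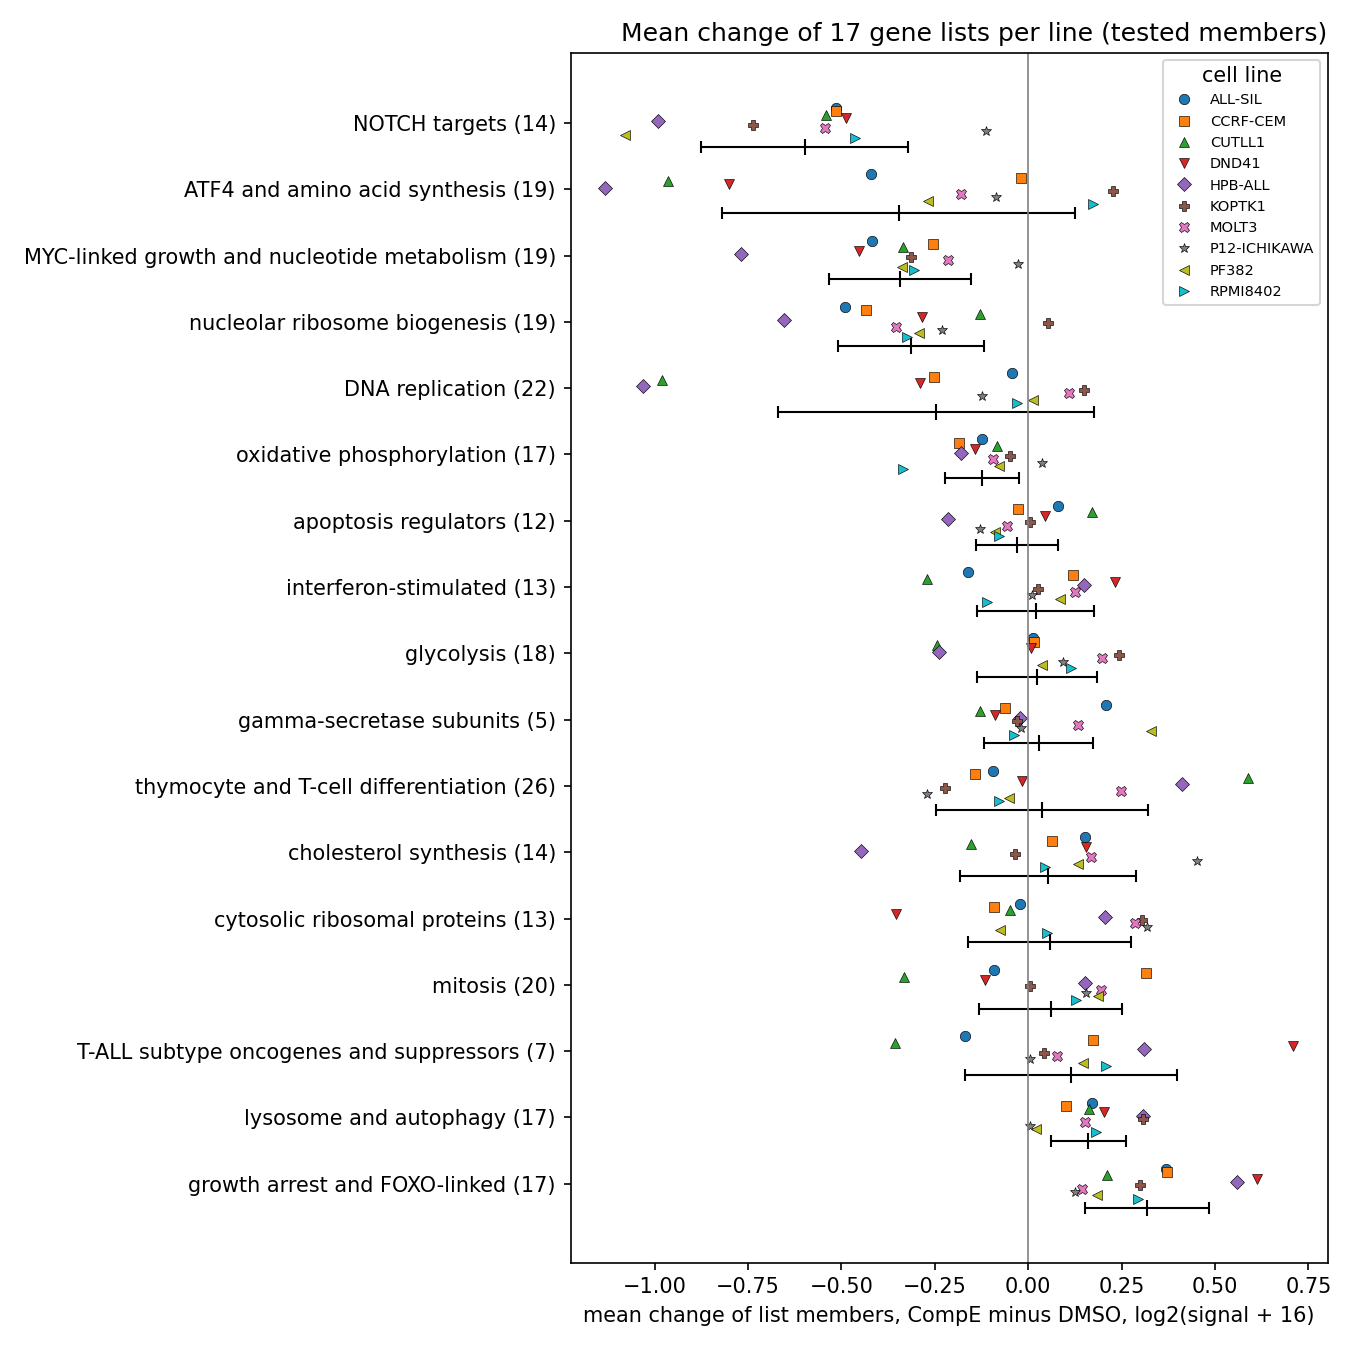
Mean change of the tested members of 17 gene lists under CompE in each of 10 lines, as CompE minus DMSO on the log2(signal + 16) scale, with the number of tested members in brackets; each symbol is 1 line and the black bar is the mean ± SD over lines. The NOTCH targets lay below 0 in 10 of 10 lines, and the DNA replication list at -1.03 in HPB-ALL and -0.98 in CUTLL1.

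Over these same arrays the markers of other cell types stayed dim, with median signals of 8.08 to 28.8 per list. None passed Benjamini-Hochberg over the 5 lists: mean changes were 0.28 for erythroid (exact p = 0.0273, adjusted 0.088), 0.14 for myeloid (exact p = 0.0352, adjusted 0.088), 0.21 for fibroblast (adjusted 0.16), 0.12 for B-cell (adjusted 0.276) and 0.08 for epithelial markers (adjusted 0.439). The B-cell gene CD79A, named after its level was seen, reached 2470 in DND41.

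The lines differed in how much they changed. Genes over 2-fold between the pair of arrays numbered 97 in CCRF-CEM, 167 in P12-ICHIKAWA, 193 in ALL-SIL, 224 in CUTLL1, 226 in RPMI8402, 262 in PF382, 437 in MOLT3, 524 in HPB-ALL, 651 in DND41 and 1229 in KOPTK1. With 1 array per condition these counts have no test within a line. The change of NOTCH targets without MYC was set against that of 5 other lists, against MYC and against the targets' own DMSO level, and none of these 7 relations passed Benjamini-Hochberg. The highest r was 0.663 between the change of NOTCH targets without MYC and that of the MYC-linked list (permutation p = 0.0411, adjusted 0.167; rho = 0.394, permutation p = 0.263; r = 0.568 without HPB-ALL and PF382). With MYC itself r was 0.392 (permutation p = 0.261, adjusted 0.39; rho = 0.200, permutation p = 0.58; r = 0.425 without the same lines). With cholesterol synthesis r was 0.646 (permutation p = 0.0478, adjusted 0.167; rho = 0.503, permutation p = 0.144; r = 0.82 without them). The nucleolar list had r = 0.345 (permutation p = 0.326, adjusted 0.39; rho = 0.139, permutation p = 0.708) and rested on HPB-ALL and PF382, without which r was -0.096. DNA replication had r = 0.351 (permutation p = 0.334, adjusted 0.39; rho = 0.03, permutation p = 0.947; r = 0.224 without them) and mitosis r = -0.142 (permutation p = 0.704, adjusted 0.704; rho = -0.139, permutation p = 0.708; r = 0.319 without them). The DMSO level of NOTCH targets and their change had r = -0.475 (permutation p = 0.161, adjusted 0.376; rho = -0.612, permutation p = 0.0667; r = -0.535 without CUTLL1 and HPB-ALL). The same DMSO array enters both values, in the change with a minus sign. Noise alone can therefore give a negative r, which the permutation does not allow for.

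**Figure D3:**
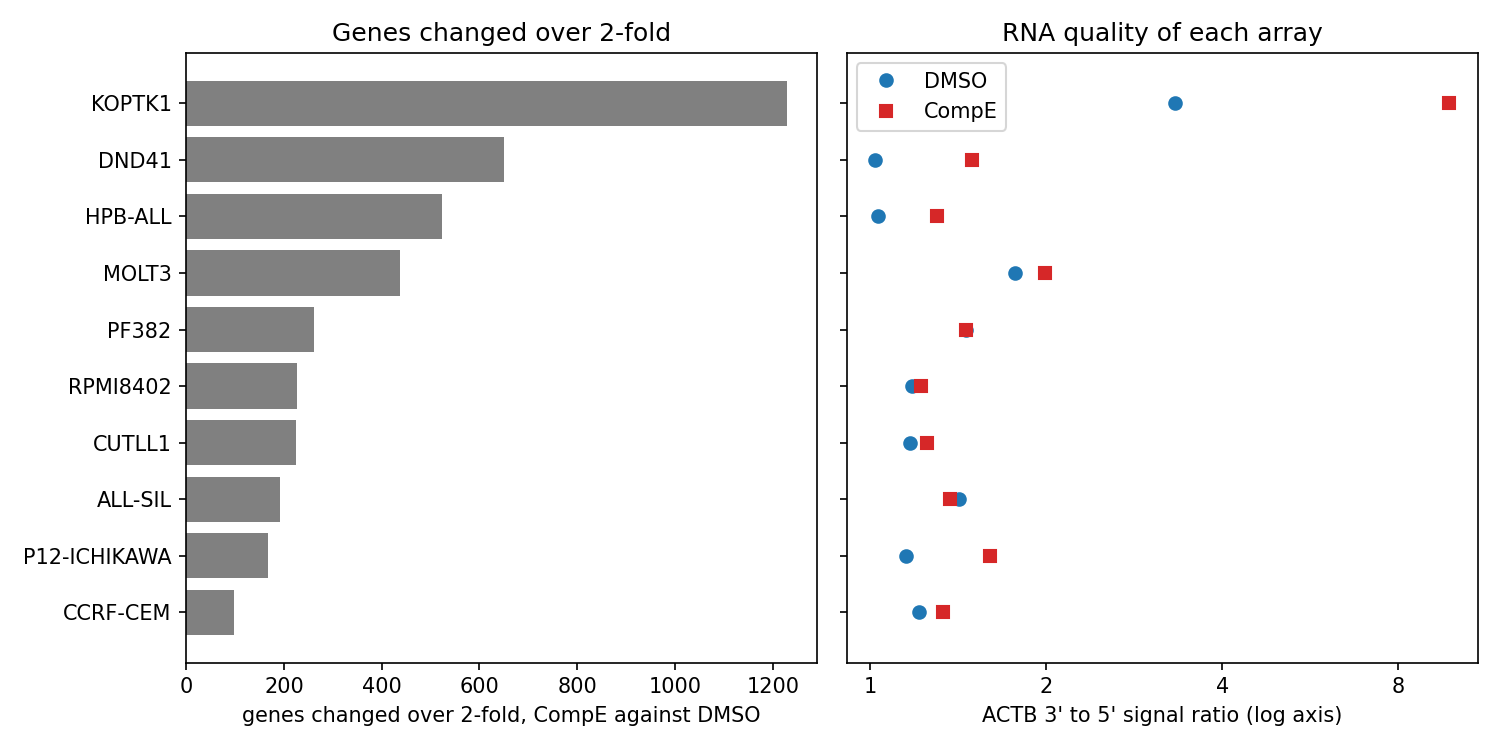
Number of genes changed over 2-fold under CompE per line (left, bars from 0) and the ratio of 3' to 5' signal of ACTB on each array (right, log axis; circles DMSO, squares CompE). KOPTK1 had 1229 such genes and ratios of 3.32 in DMSO and 9.76 in CompE.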

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

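The test of BioB against dim probe sets was chosen after the values it explains were seen; the tests of other splits, of KOPTK1 and of the signal of risen genes were written before their results. In 120 groups of 10 lines or arrays, 12 held a value far from the nearest of the others, and 92 of the groups were named genes. For independent groups with normal values chance gives 1 in 20. These groups share arrays, and some genes were picked for large changes, so the count is not a test against that rate.

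Exchanging the DMSO and CompE labels within lines gave a test of chance for the gene counts. Of 100 such splits, 1 gave as many genes as the real 552, namely the real split itself. The highest other gave 334, with 1 line exchanged. Chance is therefore an unlikely cause of the count of genes. It is not excluded, since only a part of the possible splits was run and the real split is among the 100. Nor can such splits tell an effect of CompE from a difference in array quality that moved with treatment. For the 8 gene lists called at the preset correlation, 13 of 100 splits gave as many, and the highest other gave 11, so chance cannot be excluded for the number of lists.

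KOPTK1 stood apart in several measures. It had 1229 genes over 2-fold (next 651 in DND41), ACTB ratios of 3.32 in DMSO (next 1.77) and 9.76 in CompE (next 1.99), and a GAPDH ratio of 2.33 in CompE (next 1.33). If RNA degradation gave its many changes, probe sets of 1 gene should disagree more in KOPTK1: the spread of their disagreement was 1.195 times that of the highest other line (95% interval 1.144 to 1.242), above equality but under the bound set in advance, so by this test degradation and a line-specific response cannot be told apart. The disagreement also grows with the size of a line's changes, whose SD over genes was 0.726 in KOPTK1 and 0.579 in DND41. The probe sets compared were the brightest of each gene and were not ordered by distance from the 3' end. Over the 1031 genes called without KOPTK1, its changes followed the mean of the other lines with a slope of 0.124 (95% interval -0.006 to 0.251), in the low range that degradation as their whole cause predicts. Slopes of the other lines, each over the genes called without that line and so over other sets of genes, ranged from 0.279 in P12-ICHIKAWA (541 genes) to 1.667 in HPB-ALL (181 genes). A line-specific response, which no array here can test, may give the same slope. KOPTK1 kept a NOTCH target mean of -0.74, but this includes its MYC change of -3.85. Without MYC its mean was -0.497, with the other lines between -0.973 in PF382 and -0.162 in P12-ICHIKAWA.

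Genes higher in CompE came with higher dim signals. The 8886 probe sets left out as dim had line medians that averaged 0.11 ± 0.140 higher in CompE, above 0 in 7 of 10 lines (exact p = 0.0469). A raised floor as the whole cause of the 303 genes that rose is argued against by their signals: 72.6% had a mean DMSO signal above 200, where a shift of a few units is small. That mean is over the 10 lines, so such a gene may still be dim in some of them. Risen genes were also dimmer than fallen ones: 90% of the latter lay above 200, and median DMSO signals were 383 and 651. The median change of all tested genes was 0.091, 0.038 and 0.014 from the lowest to the highest of 3 equal classes of signal. A raised floor as a part of the cause therefore stays open. For the 58 risen genes in the lowest class it stays open as the whole cause: 31 of them were also called with quantile normalization. In the middle class 101 of 111 were, and in the highest 132 of 134. With signals floored at 64, a setting that makes dim values constant and so cannot decide, 13 of the 58 were called. In the lowest class it kept 13 of 24 fallen genes, a larger share than of the risen ones. In the middle class that setting kept 58 of 111 risen and 45 of 87 fallen genes. In the highest class it kept 87 of 134 risen and 91 of 138 fallen genes. A larger scaling factor on the CompE arrays may have raised the floor, but across lines the BioB change and the dim change had r = 0.012 (permutation p = 0.973, 95% interval -0.622 to 0.637; rho = -0.018, permutation p = 0.974; r = 0.016 without the 2 lines farthest in BioB), too wide to decide; no biological explanation of the dim signals was tested.

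Other single values far from the rest were changes of 3.64 for RECK in MOLT3 (next 1.58), 3.98 for TENM1 in HPB-ALL (next 1.58), 3.18 for CD96 in HPB-ALL (next 1.18), -0.99 for CFLAR in RPMI8402 (next -0.46), -1.26 for HK2 in HPB-ALL (next -0.56), -0.32 for NCSTN in DND41 (next 0.10), -1.38 for APH1B in KOPTK1 (next -0.15) and -0.49 for MYB in HPB-ALL (next 0.05).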

How the results depend on the processing

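The ACTB ratio and the 10th percentile of signal as covariates, the floor at 64, the array quality without KOPTK1 and all alternatives for the 3 gene families were chosen after the data were seen; the other alternatives were fixed before. The NOTCH target list stayed lower and past the threshold under all 14 alternatives run for it (adjusted p 2.08e-05 to 0.0476) and without any 1 line. The cause of the changes below was not tested unless a reason is given. The random block, the fit without a trend and the robust fit were not run for gene lists. Dim signals limit the rest: a MAS5 signal near the floor carries little information.

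The count of 552 genes depended on pairing: without the replicate block 0 genes were called in limma (369 at an unadjusted p under 0.05), since lines differ more than treatments. Exact sign-flip tests called 0 (1851 unadjusted), with 259 genes at the smallest p they can give (0.00195) and a smallest adjusted p of 0.058. With the 10th percentile as a covariate 0 were called (1045 unadjusted): HES1 went from -1.71 ± 0.304 to -1.68 ± 0.390, MYC from -1.5 ± 0.282 to -1.36 ± 0.356, CR2 from -1.95 ± 0.393 to -1.25 ± 0.401 and NOTCH3 from -1.34 ± 0.233 to -0.92 ± 0.236. Changes shrank or their errors grew, and fewer small p-values were left to adjust over. The ACTB ratio as a covariate left 318 genes (154 higher, 164 lower; 207 of them among the 552), the floor at 64, which makes dim values constant, left 321 (166 and 155), leaving out CCRF-CEM, MOLT3 and P12-ICHIKAWA, the 3 lines whose DMSO label names another medium, left 298 (157 and 141; fewer samples), and a change of at least 1.5-fold left 103 (59 and 44). Median centring gave 200 higher, and the fit without a trend 162 lower. Leaving out 1 line gave 181 (HPB-ALL) to 1031 (KOPTK1) genes, 96 to 562 higher and 85 to 469 lower; of the 552, 541 were among the 1031. The other alternatives gave 375 to 603 genes. Without the filter, cell line took 82.1% and treatment 3.6% of the variation.

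With an estimated correlation, adjusted p was 0.064 for the nucleolar and the MYC-linked list, 0.375 for DNA replication, 0.269 for ATF4, 0.092 for growth arrest, 0.179 for oxidative phosphorylation and 0.105 for lysosome and autophagy. Fry gave 0.195 for DNA replication and 0.125 for ATF4. Lysosome and autophagy had 0.0733 without the block, 0.0901 with the mean of probe sets and 0.0556 with the ACTB ratio. Cytosolic ribosomal proteins were lower with quantile normalization (0.0176), without the 3 lines (0.81) and with the ACTB ratio (0.926), and ranged from 0.033 (without DND41) to 0.88 when 1 line was left out.

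Lists never called also turned direction. Glycolysis was lower with quantile normalization (0.726), median centring (0.876), pseudocount 64 (0.998), no filter (0.742), the mean of probe sets (0.98), without the 3 lines (0.585), with the ACTB ratio (0.626) and with the floor (0.912). Gamma-secretase subunits were lower without the block (0.927), with quantile normalization (0.775), median centring (0.972), pseudocount 64 (0.998) and no filter (0.945). Interferon-stimulated genes were higher without the block (0.927), with pseudocount 64 (0.998), the 60th percentile filter (0.224), the mean of probe sets (0.973), the floor (0.754) and fry (0.623). Cholesterol synthesis was lower with no filter (0.979), the mean of probe sets (0.898) and without the 3 lines (0.599). Thymocyte genes were lower without the block (0.927), mitosis without the 3 lines (0.585; mean per line -0.01), and T-ALL oncogenes with the 10th percentile (0.956). When 1 line was left out, adjusted p ranged from 0.636 to 0.977 for glycolysis, 0.82 to 0.99 for gamma-secretase, 0.793 to 0.977 for interferon, 0.378 to 0.977 for cholesterol and 0.499 to 0.99 for thymocyte genes.

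Genes not called that turned were RPS14 with quantile normalization (-0.01), NOTCH1 and APH1A with median centring (-0.011 and -0.004) and with the ACTB ratio (-0.123 each), PSEN2 with the floor (0.005), and with the mean of probe sets NUSAP1 (-0.035), TOP2A (-0.008), LEF1 (-0.045), PGK1 (-0.027) and MYB (-0.256). Without 1 line NOTCH1 ranged from -0.064 to 0.077 and APH1A from -0.031 to 0.082. The mean of DNA replication per line was -0.287 with median centring (exact p = 0.0371) and -0.292 to -0.161 when 1 line was left out. Without HPB-ALL and PF382, the relation of NOTCH targets with the nucleolar list turned to r = -0.096 and that with mitosis to 0.319. The GAPDH ratio had exact p = 0.0625 without KOPTK1. Of the 51 called named genes, 33 passed with the ACTB ratio, 40 with a random block and 29 with the floor. In fits without 1 line, 25 were lost at least once: EIF4EBP1, HELLS, ID1, PDAP1, EIF5A, SH3GL3, RECK, RHEX, TENM1, CD96, SLC6A13, CACNG4, MRTO4, WDR12, NIP7, MTHFD2, LCK, GATA3, CD3G, CCNG2, TXNIP, BCL2L1, ATP5MC1, GAPDH and SHQ1.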

Other observations

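The tests in this part were chosen after results were seen. MRPL12, EIF5A and EIF2S3 had stood among the largest falls, so mitochondrial ribosomal proteins and translation initiation factors were tested without them. Genes named EIF4EBP, EIF2AK or EIF4ENIF, EIF4EBP1 among them, were left out because they are not initiation factors. For chaperonin subunits, the last of the 3 gene families, no gene was left out for having been seen. Mitochondrial ribosomal proteins, which build the ribosomes of mitochondria, fell as a group: 18 of 48 fell and 0 rose, 45 lay below 0, and the mean per line was -0.26 ± 0.130 (SD, n = 10), below 0 in all 10 lines. MRPS15 fell by 0.65 ± 0.1 (limma adjusted p = 0.00448) and MRPL42 by 0.53 ± 0.137 (adjusted p = 0.031). Camera over the 3 families gave adjusted p = 6.45e-18, and adjusted p = 0.0181 with an estimated correlation. All 3 families were also lower with quantile normalization and median centring, but with the latter none passed with an estimated correlation (adjusted p = 0.0569, 0.0626 and 0.0626 in the order given here).

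Of 34 translation initiation factors, 4 fell and 0 rose: EIF2B3 by 0.56, EIF1AX by 0.52, EIF2S1 by 0.40 and EIF3I by 0.35. Of the 34, 21 lay below 0. The family mean was -0.11 ± 0.064, below 0 in 9 lines, and camera gave adjusted p = 2.46e-04, and 0.0187 with an estimated correlation. Of 8 tested genes for subunits of the cytosolic chaperonin, which folds actin and tubulin (CCT6A and CCT6B encode forms of the same subunit, and TCP1 was not tested), CCT6A fell by 0.33 and CCT3 by 0.30, and 7 lay below 0 (camera adjusted p = 2.33e-04, and 0.0203 with an estimated correlation; 0.0889 with the ACTB ratio as a covariate and 0.0592 without KOPTK1). Their mean per line was -0.17 ± 0.132, below 0 in 9 lines. That such families fall with MYC is a hypothesis found on the same data and was not tested further.

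The DNA replication list was lower in camera with 0 members called over all genes, a call lost with an estimated correlation (adjusted p = 0.375) and in fry (adjusted p = 0.195), and its fall may rest on a few lines. Its mean change was above 0 in 3 lines, MOLT3 at 0.11, PF382 at 0.01 and KOPTK1 at 0.15, and its spread over lines of 0.423 was larger than its mean of -0.25. As these line values had been seen before, they decide nothing; whether HPB-ALL and CUTLL1 slowed their cycle more was not measured.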
